A study of Mus musculus with 4 samples.

How the data were processed

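RNA-seq libraries from sorted mouse ILC3s were compared, 2 kept in medium and 2 stimulated with TL1A. Per the labels' protocols, cDNA was made with the SMARTer Ultra Low Input RNA Kit and libraries with standard Illumina protocols. Per the submitters' processing notes, base calling used CASAVA, alignment STAR and counting HTSeq, on genome build mm9; versions, strand setting and annotation release are not given in the sources used here. The deposited values are raw read counts per RefSeq transcript accession, per the file headers and the values, which are whole numbers with different column totals. The table held 33535 transcript rows and 5 HTSeq summary rows. The summary rows name no gene and were left out of library sizes and tests; they held 69.9% to 71.3% of all numbers in a column, as reads not uniquely aligned (13351986 to 15146857 per library), without a feature or ambiguous between features. Not uniquely aligned entries can include several alignments of one read. As the deposited count rows are transcripts, the authors counted per transcript, so a read in an exon shared by several transcripts is ambiguous, and a gene with several transcripts is counted only over parts that belong to one of them. Ambiguous reads were 33.7% to 34% of assigned plus ambiguous reads. Genes that share sequence with copies or pseudogenes lose reads to the not uniquely aligned class, and overlapping or antisense genes cannot be told apart where the strand is not used.

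Transcript accessions were matched to gene symbols through a RefSeq gene table of assembly GRCm38.p6, used for names only because the build differs from mm9, so that no coordinates are given. Of the rows, 33154 matched, giving 23962 symbols, and 381 rows with 0.85% to 0.9% of assigned reads kept their accession as a name. The plan fixed before the data were examined spoke of genes, whereas the rows turned out to be transcripts. Rows of the same gene were therefore summed, which left 19359 genes with 1 row and 4984 with several; tests of each row on its own and of single-row genes only were added afterwards as alternatives.

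Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (filterByExpr with a minimum count of 10, glmQLFit and glmQLFTest, group as the only term, TMM factors of 1.09 and 1.09 for medium and 0.908 and 0.921 for TL1A, two-sided, Benjamini-Hochberg adjusted p under 0.05). CPM values were scaled by TMM effective library size and are given as mean ± SD of 2 libraries. The standard error of a log2 fold change was its size divided by the square root of the F statistic. An exact permutation test of 2 against 2 libraries cannot go below p = 0.333, so single genes rest on the spread pooled across genes. The common biological coefficient of variation was 0.12, and the chi-square per degree of freedom was 12.1 between the medium libraries and 7.75 between the TL1A libraries, so neither pair was a repeat deposit of one library. The titles give the groups shared replicate numbers but do not say what a number stands for, so the number was not used as a block in the main test.

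Before the data were examined, 22 gene lists were fixed: NF-κB genes, ILC3 effector cytokines, TNF superfamily and costimulatory ligands, TNF receptors, chemokines, MHC class II presentation, ILC3 identity, immediate early and AP-1 genes, JAK-STAT feedback, interferon response, cell cycle, glycolysis, cholesterol synthesis, endoplasmic reticulum stress, markers of T cells, B cells, myeloid cells, ILC1 and NK cells, ILC2s, epithelial and stromal cells and red cells, and mitochondrially encoded genes. The 19 lists with at least 3 tested members were tested against other genes with camera (limma 3.58.1) at a preset correlation of 0.01. The mitochondrially encoded list had no member among the matched rows and could not be used as a sign of RNA quality. With an estimated correlation, 0 of the 9 lists called by camera held at an adjusted p under 0.05. Of the 19, 8 had an unadjusted p under 0.05 with that estimate, and fry called 13. Among the called lists the estimate was negative except for MHC class II presentation (0.083) and ILC1 and NK cell markers (0.058). This form of camera draws its degrees of freedom from the libraries, so 2 against 2 leave it little power. Its lost calls therefore do not show that correlation between genes undid a result. Named genes were fixed by rule before the data were examined: 7 genes of the study's question; the 10 largest increases and 10 largest decreases among passing genes with a mean of at least 10 counts and groups that did not overlap; and up to 4 members of each list with the smallest p. Some genes named by this rule are not reported here. Where a group had 0 reads the fold is a bound against 3 counts over the group, and with 1 to 3 reads a ratio with a 95% exact (Clopper-Pearson) counting interval.

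On simulated counts for the TL1A comparison (9852 genes, 200 changed), the test recovered 24% of genes changed by 0.5 on the log2 scale, 60% at 1, 88% at 2 and 90% at 3, and 5.1% of its calls were false. In the data 42.3% of tested genes passed, a far larger share than was changed here, and the simulated genes varied independently. These rates may therefore not carry over to the calls made on the data. Alternatives were other scalings (RLE, upper quartile), no low-count filter, a stricter filter, DESeq2 1.42.0, limma-voom, the replicate block, leaving out each library, an adjusted p under 0.1, camera with an estimated correlation and fry. Lists were not tested with DESeq2.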

Results

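RNA-seq was carried out on group 3 innate lymphoid cells (ILC3s) of mice. ILC3s are lymphocytes without antigen receptors that make IL-22 at mucosal surfaces. The cells were sorted as lineage-negative, CD127-positive and GFP-positive from animals with 1 reporter copy of the IL-23 receptor locus, so that GFP marks cells in which that locus is active. They were then kept in medium or stimulated with TL1A, a TNF superfamily cytokine that signals through the receptor DR3, encoded by Tnfrsf25. There were 4 libraries, 2 for each condition. The medium libraries are those not marked as stimulated. No label says whether the 2 libraries of a condition came from separate animals or cultures, so the p-values measure only the spread between these libraries, which may be technical. The libraries held 11495636 and 12222552 assigned reads for medium and 11849977 and 12605164 for TL1A. The question addressed was how TL1A changes the transcriptome of ILC3s.

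TL1A stimulation was accompanied by a broad change in expression that included cytokine, chemokine and costimulatory ligand genes. Of 9852 genes tested, 2027 were higher and 2141 were lower with TL1A at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), which together made 42.3% of the genes tested. At least 2-fold changes were found for 864 of the higher and 1043 of the lower genes, and at least 8-fold changes for 207 and 155. Log2 CPM correlated at 0.986 between the medium libraries and at 0.986 between the TL1A libraries, against 0.907 to 0.912 across conditions; these are correlations across genes, which are not independent replicates. The libraries of a group did not overlap with those of the other group for 72.2% of tested genes, where chance gives 33.3%. Of the reads counted, the 10 most abundant genes took 6.65% and 6.78% in medium and 10.9% and 10.5% with TL1A, and Actb (cytoskeletal actin) took 3.38% and 3.28% with TL1A. Uniquely placed reads outside the annotated transcripts, which can come from unspliced RNA or DNA, made up 35% and 32.3% in medium and 30.6% and 28.8% with TL1A.

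**Figure D1:**
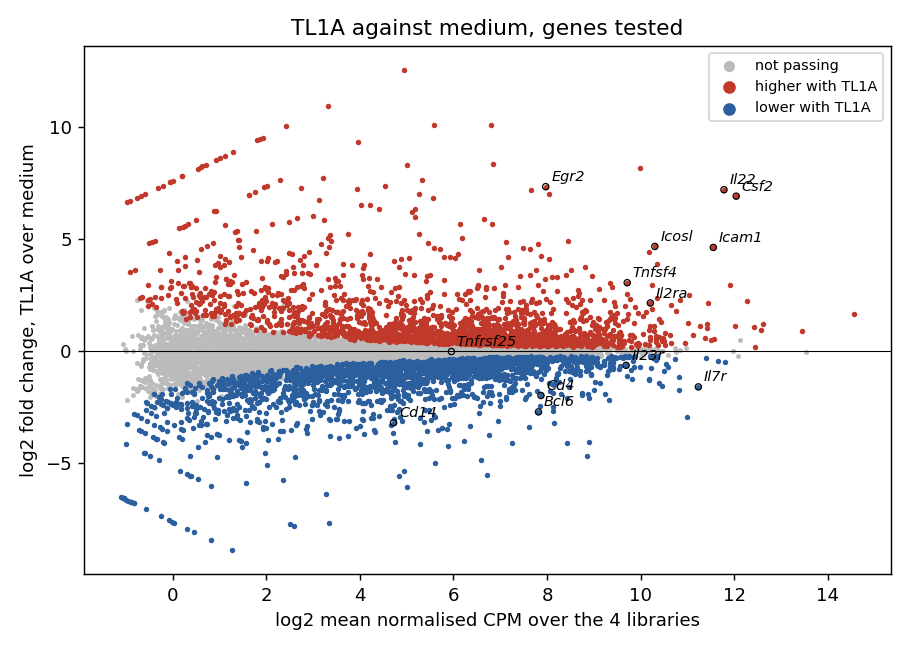
Log2 fold change (TL1A over medium, y axis) against the log2 mean normalised CPM over the 4 libraries (x axis) for the 9852 genes tested. Red points are the 2027 genes higher with TL1A, blue points the 2141 genes lower and grey points genes not passing. Values for genes at 0 counts in one condition, seen as the diagonal streaks at low abundance, depend on the prior count of the fit.

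The cytokine genes Csf2 and Il22, which encode GM-CSF and IL-22, ranked 5 and 9 by mean CPM among the tested genes of the stimulated cells, against 3002 and 3776 in medium. These ranks hold among counted reads only and are not corrected for transcript length. Genes whose reads were shared between rows or copies rank too low, and Gapdh had only 23 and 17 reads with TL1A. Il22 rose from 47.7 ± 12.4 to 6975 ± 199 CPM (SD, n = 2), a log2 fold change of 7.19 (SE 0.18, edgeR adjusted p = 2.79e-07). Iltifb, a near-identical copy of Il22 named after its values were seen, had 62 and 43 reads in medium and 5580 and 6018 with TL1A, and reads of the copies may be divided between them, so the value of either gene alone is uncertain. Csf2 rose from 69.5 ± 1.92 to 8346 ± 193 CPM, a log2 fold change of 6.91 (SE 0.07, adjusted p = 1.12e-08). Il17a, which encodes IL-17A, had 4 reads in 1 medium library and 0 in the other 3 libraries, and a count of 0 allows up to 0.253 and 0.238 CPM in the TL1A libraries (3 counts of the assigned reads per library), so a difference was not detectable at this depth. Among the 9 tested members of the list of ILC3 effector cytokines, 8 rose, none fell and 1 did not pass. Ifng rose from 0.192 ± 0.046 to 12.3 ± 0.225 CPM, on only 2 and 3 reads in the medium libraries. Lta, which encodes lymphotoxin alpha, rose by 1.89 on the log2 scale (SE 0.09). The list as a whole was higher than other genes (camera, adjusted p = 5.71e-16; adjusted p = 0.0529 with an estimated correlation).

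Most tested ligands that act on T cells and other lymphocytes rose. Tnfsf4, which encodes the T cell costimulator OX40L, rose from 180.2 ± 13.2 to 1496 ± 47.9 CPM (SD, n = 2), an 8.3-fold change (log2 fold change 3.05, SE 0.08, adjusted p = 3.09e-07). Icosl, which encodes the ligand of the costimulatory receptor ICOS, rose from 95.5 ± 0.096 to 2427 ± 16.2 CPM. Tnfsf11, which encodes RANKL, rose from 14.2 ± 0.315 to 343.9 ± 14.7 CPM, and Tnfsf8, which encodes CD30 ligand, rose by 2.18 on the log2 scale (SE 0.07). In the list of TNF superfamily and costimulatory ligands, 10 of 14 tested members rose, none fell and 4 did not pass (camera, adjusted p = 3.88e-23; adjusted p = 0.0529 with an estimated correlation). Tnfsf15, which encodes TL1A itself and was picked out after its values were seen, had 10 and 5 reads in medium and 196 and 239 with TL1A. In the TNF receptor list, 2 of 9 tested members rose, 2 fell and 5 did not pass, and the list did not stand apart from other genes (camera, adjusted p = 0.313). Fas, a death receptor gene, rose by 5.66 on the log2 scale (SE 0.28), or by 6.46 without medium replicate 2, and Tnfrsf4, the OX40 gene, rose by 1.24 (SE 0.29). Tnfrsf18 fell by 0.70 (SE 0.19) and Tnfrsf1a fell by 0.51 (SE 0.14), and both calls were lost without some single libraries: the adjusted p of Tnfrsf18 was 0.116 without medium replicate 2 and 0.0957 without TL1A replicate 2, and that of Tnfrsf1a was 0.0977 without medium replicate 1 and 0.114 without TL1A replicate 1.

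Tnfrsf25, the gene of the TL1A receptor, had 62.4 ± 7.29 CPM in medium and 61.8 ± 10.7 CPM with TL1A when its 2 deposited transcript rows were summed (log2 fold change -0.01, SE 0.15, adjusted p = 0.956), and its sign changed with the scaling (0.013 with RLE factors). Reads in exons shared by both rows were not counted, so this sum does not measure the whole gene. The rows moved apart. Transcript NM_001291010 rose by 0.58 on the log2 scale (SE 0.17, edgeR adjusted p = 0.025) and transcript NM_033042 fell from 432 and 385 reads to 148 and 206 (adjusted p = 0.0042), and the difference between the rows passed the test of unequal change within a gene (edgeR diffSpliceDGE, adjusted p = 0.00701).

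**Figure D2:**
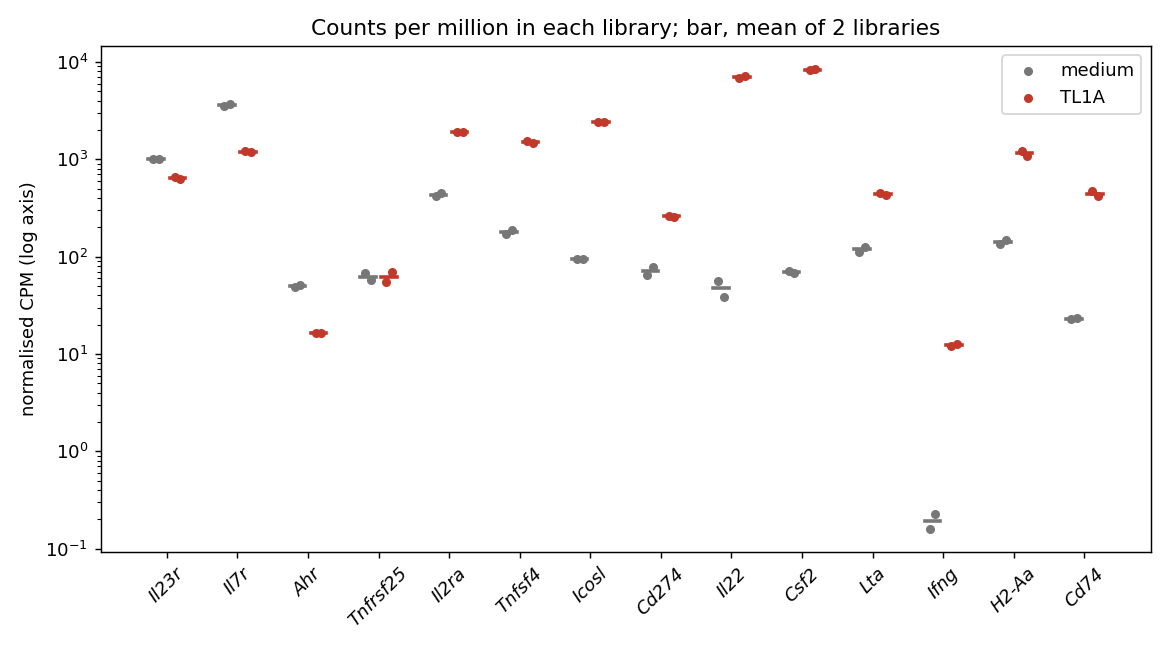
Normalised CPM (log axis) of 14 genes in each library, with medium in grey and TL1A in red; points are the 2 libraries of a condition and bars their mean. With TL1A the means of Il22 and Csf2 lie at 6975 and 8346 CPM, and those of Tnfrsf25 lie at 62.4 CPM in medium and 61.8 CPM with TL1A. The Tnfrsf25 values sum 2 transcript rows that moved apart and leave out reads shared between them.

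Each of the 11 tested chemokine genes rose, with a median log2 fold change of 5.19 (camera, adjusted p = 1.56e-33; adjusted p = 0.0529 with an estimated correlation). Cxcl16, which encodes the ligand of CXCR6, rose from 2.73 ± 0.264 to 398.5 ± 28.5 CPM. Ccl5 rose from 29.1 ± 3.71 to 499.1 ± 1.62 CPM, Cxcl10 from 4.23 ± 0.69 to 141.6 ± 23.3 CPM and Ccl22 from 28.8 ± 0.335 to 204 ± 0.65 CPM. Genes of NF-κB signalling, the pathway that TNF receptors feed into, also rose: 15 of 18 tested members were higher, 1 was lower and 2 did not pass (camera, adjusted p = 3.6e-19; adjusted p = 0.0529 with an estimated correlation). The adhesion molecule gene Icam1 rose from 233.6 ± 12.8 to 5764 ± 164 CPM. Gadd45b rose by 4.57 on the log2 scale (SE 0.09), the inhibitor gene Nfkbie by 2.86 (SE 0.10) and the adaptor gene Traf1 from 630.4 ± 62.9 to 3571 ± 209 CPM. Nfkbiz, of the same list, had 0 reads in every library; it has 3 deposited rows, and reads shared between rows were not counted.

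Genes of antigen presentation by MHC class II were higher for 6 of 8 tested members, with 1 lower and 1 not passing (camera, adjusted p = 7.97e-12; adjusted p = 0.078 with an estimated correlation). Adjusted over the list alone, 7 were higher and 1 lower. Cd74, the invariant chain gene, rose from 23.1 ± 0.529 to 442.7 ± 36 CPM, and the class II chain genes H2-Eb1 and H2-Aa rose by 3.74 (SE 0.10) and 3.02 (SE 0.09) on the log2 scale. H2-DMb1, whose product helps to load peptides, rose by 2.24 (SE 0.20). Among other cells that present antigen, both tested B cell markers, Blk and Cd79b, rose, while Ms4a1 and Pax5 had 0 reads in every library. In the myeloid marker list, 3 of 11 tested members fell, 1 rose and 7 did not pass (camera, adjusted p = 0.0718). Cd14 went from 47.5 ± 2.53 to 5.22 ± 0.67 CPM, Fcer1g fell by 1.25 (SE 0.07), Mpeg1 fell by 1.90 (SE 0.50) and the macrophage marker Adgre1 rose by 0.91 (SE 0.27). The Adgre1 call was lost with the replicate number as a block (adjusted p = 0.0524), without medium replicate 2 (0.099) and without TL1A replicate 2 (0.141). The Mpeg1 call was lost without medium replicate 2 (0.0733), and its log2 fold change was -2.98 without TL1A replicate 1 and -1.26 without TL1A replicate 2. The list passed as lower without medium replicate 1 (0.031) or without TL1A replicate 2 (0.0363), and over single-row genes (0.0459).

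Members of the fixed ILC3 identity list moved in both directions. Of 18 tested members, 9 fell, 5 rose and 4 did not pass, and the list did not stand apart from other genes (camera, adjusted p = 0.87). Il7r, which encodes the sorting marker CD127, fell from 3606 ± 77.2 to 1200 ± 12.5 CPM. Il23r, the locus of the reporter, fell from 1001 ± 7.93 to 647.6 ± 22.2 CPM (log2 fold change -0.63, SE 0.06, adjusted p = 0.000188). Zbtb16 fell by 3.03 (SE 0.27), Il1r1 by 2.14 (SE 0.32), Ahr by 1.61 (SE 0.14) and Tox by 1.22 (SE 0.07) on the log2 scale. In the other direction, Ncr1, which encodes the activating receptor NKp46, rose from 15.5 ± 0.748 to 431.7 ± 13.9 CPM. The IL-2 receptor gene Il2ra rose from 434.5 ± 19.7 to 1927 ± 0.126 CPM, and the decoy receptor gene Il1r2 by 4.57 on the log2 scale (SE 0.16). Id2 and Runx3 rose by only 0.49 (SE 0.07) and 0.46 (SE 0.07).

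Markers of other lymphocytes gave no single direction. In the list of ILC1 and NK cell markers, Ccl5 (shared with the chemokine list) and Gzmb rose, Gzma and Klrk1 fell and 2 of 6 tested members did not pass; adjusted over the list alone, 4 rose and 2 fell. Gzmb, a cytotoxic granule protease gene, rose by 4.34 (SE 0.46; 5.57 without medium replicate 1, 3.69 without medium replicate 2) and Gzma, another granzyme gene, fell by 2.32 (SE 0.33). Klrk1, the gene of the receptor NKG2D, fell by 2.56 (SE 0.61); its adjusted p was 0.0516 without medium replicate 1 and 0.0715 without TL1A replicate 2, and its log2 fold change was -3.74 without TL1A replicate 1 and -1.88 without TL1A replicate 2. The camera call of this list (adjusted p = 0.0161; adjusted p = 0.291 with an estimated correlation) was lost with no low-count filter (0.362), with limma-voom (0.285), and without medium replicate 2 (0.0719), TL1A replicate 1 (0.13) or TL1A replicate 2 (0.0537). Among the 7 tested ILC2 markers, Klrg1 rose by 2.29 (SE 0.10), Il17rb fell by 1.51 (SE 0.25), Il1rl1, the IL-33 receptor gene, fell by 2.37 (SE 0.48; -3.65 without TL1A replicate 1, -1.68 without TL1A replicate 2), and 4 did not pass. Hpgds, among those, had a log2 fold change of -1.08 (SE 0.43, adjusted p = 0.0827) and passed with no low-count filter (0.0177), with the replicate number as a block (0.0216), without medium replicate 1 (0.0177) and without TL1A replicate 2 (0.0186, log2 fold change -1.67). Without medium replicate 2 its log2 fold change was -0.48 (adjusted p = 0.456). The ILC2 list was not called (camera, adjusted p = 0.705, direction higher, with a median of -0.43 and a mean of -0.07). Among T cell markers, Cd4, which some ILC3s also carry, fell by 1.97 (SE 0.12) and Cd28 fell by 3.03 (SE 0.70), while 3 of 5 tested members did not pass (camera, adjusted p = 0.206). Without medium replicate 2 the log2 fold change of Cd28 was -1.996 (adjusted p = 0.11), and without medium replicate 1 it was -3.61. Lat had a log2 fold change of -0.23 (SE 0.12), and Cd3e had 0 and 16 reads in medium and 20 and 16 with TL1A, with a call (adjusted p = 0.0136) only when medium replicate 2 was left out. Only 2 B cell markers were tested, and both rose: the kinase gene Blk by 2.58 (SE 0.08) and Cd79b by 1.35 (SE 0.16). Ms4a1 and Pax5, markers of the same cells, had 0 reads in every library. Of the epithelial and stromal markers, 3 were tested (camera, adjusted p = 0.409): Krt18 fell from 5.32 ± 3.29 to 0.272 ± 0.141 CPM (log2 fold change -4.25, SE 0.70; -3.43 without medium replicate 1, -4.86 without TL1A replicate 1), Vil1 had a log2 fold change of -0.13 (SE 0.58) and Pecam1 one of -0.60 (SE 0.32). No red cell marker had enough reads to be tested.

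**Figure D3:**
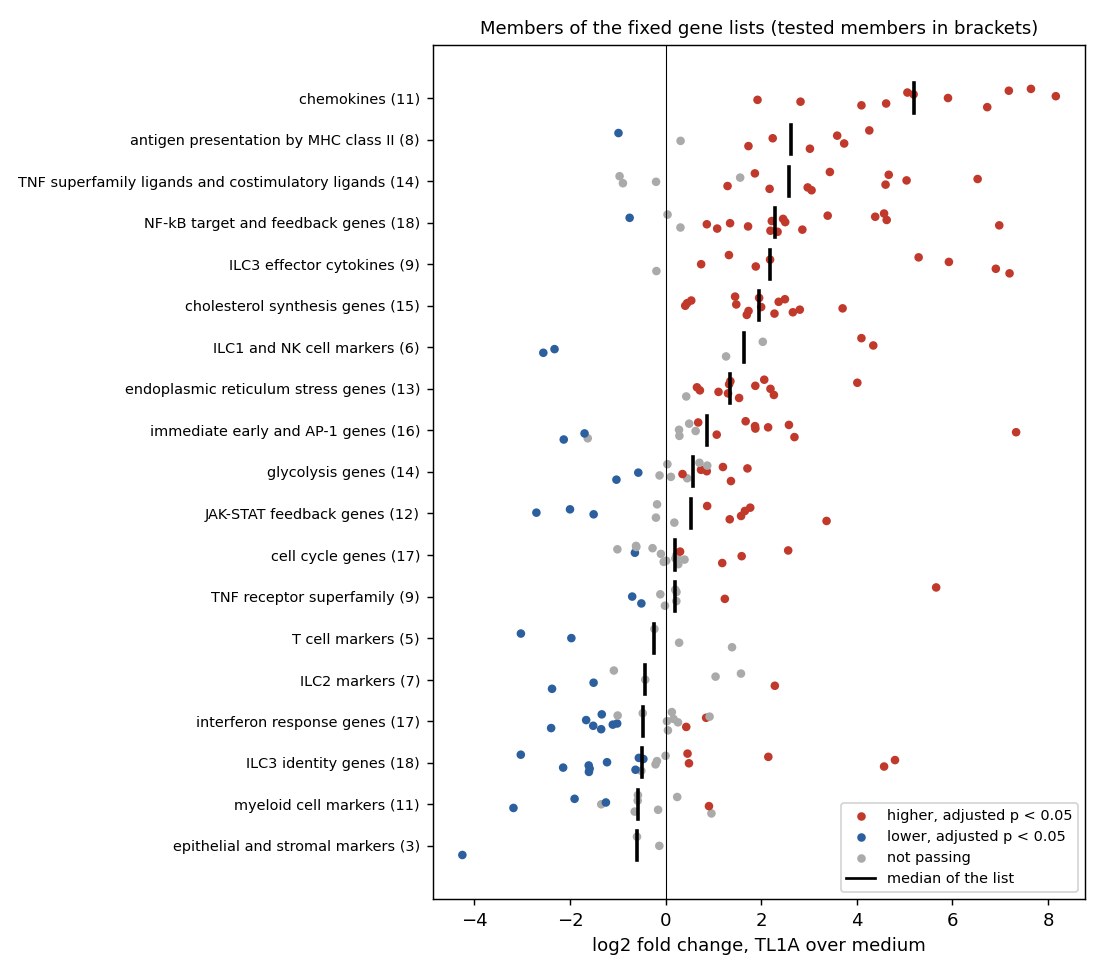
Log2 fold change (TL1A over medium, x axis) of each tested member of the 19 lists with at least 3 tested members, with the number tested in brackets. Red points passed as higher, blue points as lower, grey points did not pass, and black bars mark the list medians. The chemokine members all lie above 0, while the ILC3 identity genes spread from -3.03 to 4.80.

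Most tested cholesterol synthesis and endoplasmic reticulum stress genes were higher. A smaller share of the tested glycolysis and cell cycle genes rose, and several members of those lists were barely counted. All 15 tested cholesterol synthesis genes rose (camera, adjusted p = 1.64e-14; adjusted p = 0.0529 with an estimated correlation). Sqle, which encodes squalene epoxidase, rose from 80.6 ± 1.37 to 510.3 ± 19.1 CPM, Cyp51 by 2.37 (SE 0.08) and Msmo1 by 1.96 (SE 0.07) on the log2 scale. Of the endoplasmic reticulum stress genes, 12 of 13 rose and 1 did not pass (camera, adjusted p = 8.63e-09; adjusted p = 0.0775 with an estimated correlation). The chaperone gene Hsp90b1 rose from 628 ± 19.9 to 3020 ± 60.8 CPM, Pdia6 by 1.88 (SE 0.06), Calr by 2.19 (SE 0.18) and Pdia4 by 0.66 (SE 0.06). Of the glycolysis genes, 6 of 14 rose, 2 fell and 6 did not pass, and the list was not called (camera, adjusted p = 0.206). The fry test, which does not compare a list with other genes, called it higher (adjusted p = 0.0193). Gapdh had only 8 and 6 reads in medium and 23 and 17 with TL1A. Eno1 had 1 and 2 reads in medium and 5 and 2 with TL1A, so such members were hardly measured. The glucose transporter gene Slc2a1 rose by 1.37 (SE 0.09), Pgk1 by 1.20 (SE 0.16), Tpi1 by 0.74 (SE 0.09) and Pfkl by 0.35 (SE 0.06). Cell cycle genes mostly did not pass: 4 of 17 rose, 1 fell and 12 did not pass (camera, adjusted p = 0.399). The fry test called this list higher too (adjusted p = 0.00703). Mcm5 and Bub1, each with several deposited rows, had 0 reads in every library. Mcm3 rose by 1.59 (SE 0.11), Top2a by 1.19 (SE 0.15) and Rrm2 by 2.56 (SE 0.33), and Mcm7 fell by 0.64 (SE 0.12).

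Transcriptional response genes were mixed. Among immediate early and AP-1 genes, 9 of 16 rose, 2 fell and 5 did not pass (camera, adjusted p = 2.19e-06; adjusted p = 0.0813 with an estimated correlation), and 10 rose when adjusted over the list alone. The transcription factor gene Egr2 rose from 3.07 ± 0.85 to 498.5 ± 24.8 CPM, Fosl2 by 2.70 (SE 0.12), Batf by 1.67 (SE 0.08) and Ier5 by 1.88 (SE 0.12). In the JAK-STAT list 6 of 12 rose, 3 fell and 3 did not pass (camera, adjusted p = 0.399; called as higher over single-row genes, 0.0346). The feedback inhibitor gene Cish rose from 30.2 ± 2.89 to 312.2 ± 26.4 CPM and Il2rb, another IL-2 receptor chain gene, rose by 1.77 (SE 0.09). The repressor gene Bcl6 fell from 390.5 ± 55 to 60.1 ± 11.2 CPM and the survival gene Bcl2 fell from 419.8 ± 42.9 to 147.9 ± 4.79 CPM. In the interferon response list 7 of 17 fell, 2 rose and 8 did not pass (camera, adjusted p = 0.409). Usp18 fell by 1.33 (SE 0.12), Ifit3 by 2.39 (SE 0.49; -3.01 without TL1A replicate 2) and Oas1a by 1.10 (SE 0.28), whereas Gbp2 rose by 0.85 (SE 0.07). For every list not given a second count, the count adjusted over the list alone was the same as that over all genes.

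The largest fitted increases were in genes with almost no reads in medium, where only a bound or a wide interval on the fold can be given. Madcam1, an adhesion molecule gene, had 0 reads in both medium libraries and 709 and 657 with TL1A, which is at least 528-fold higher against a floor of 3 counts over the group. On the same floor, Adamts14 was at least 172-fold higher, C730036E19Rik 92.7-fold, Ces2c 65.7-fold, Mrgpra1 62.2-fold, Sh2d4a 60.7-fold and the vitamin D hydroxylase gene Cyp27b1 42.5-fold. Idi2, of the isoprenoid pathway, had 1 read in each medium library and 1004 and 1130 with TL1A, a ratio of 1240 with a 95% exact counting interval from 342 to 10200. The trefoil factor gene Tff1 had a ratio of 805 (interval 144 to 31800), and Ceacam15 had 1 and 4 reads in medium and 2454 and 2490 with TL1A (log2 fold change 10.09, SE 0.23; 9.47 without medium replicate 1, 11.28 without medium replicate 2). In the other direction, Rd3l had 56 and 69 reads in medium and 0 in both TL1A libraries, at least 35.9-fold lower. Pbld1 was at least 26.5-fold lower, Gprin3 20.7-fold, Spata46 18.7-fold, C030034L19Rik 15.2-fold, Tmem121b 15-fold and Krt83 14.1-fold. The mast cell protease gene Cpa3 had 212 and 314 reads in medium and 2 and 0 with TL1A, a ratio of medium to TL1A of 227 (interval 62.5 to 1880). Egfl6 had a ratio of 252 (interval 44.9 to 9980) and the receptor gene Cd200r2 one of 270 (interval 48.1 to 10700). Mrgpra1, Ces2c, Pbld1, Krt83 and Cd200r2 belong to families of similar genes, so reads may be divided between copies. Single libraries moved several of these fitted log2 fold changes, which depend on the prior count where a group is left at 0. Tff1 moved from 9.31 to 11.53 without medium replicate 1 and 8.45 without medium replicate 2. Without TL1A replicate 1 and without TL1A replicate 2, Cpa3 moved from -7.66 to -10.98 and -6.68, Egfl6 from -7.68 to -10.14 and -6.77, and Cd200r2 from -7.77 to -6.96 and -10.20. Mrgpra1 moved from 9.46 to 8.76 without TL1A replicate 1, Gprin3 from -8.06 to -7.40 without medium replicate 2 and Tmem121b from -7.59 to -8.20 without medium replicate 1. These intervals and floors cover counting error only.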

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

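The tests of each deposited row, of single-row genes and of the crossed pairing were chosen after seeing the data. Counts of genes stayed within 1.5 times the main counts of 2027 higher and 2141 lower under each alternative run. DESeq2 gave 1929 and 1740, upper-quartile factors 1819 and 2378, no low-count filter 2158 and 2285, and each deposited row on its own 2057 and 2168. Leaving out 1 library, where the lone library is assumed to vary like the other group, gave 1596 to 1956 higher and 1597 to 1822 lower genes, and 74.1% to 82.1% of the main calls were shared in the same direction. The replicate numbers share 2 pairs only, with a correlation of deviations of -0.105 over all tested genes; the replicate block gave 1736 higher and 1806 lower genes, and of the named genes it ended the call of Adgre1 and called Hpgds (adjusted p = 0.0216). Pairing the numbers crosswise gave 2295 higher and 2439 lower genes. Of the 99 named genes tested, 93 passed, which the naming rule largely fixed, because most were picked from these data for large changes or small p-values. Tnfrsf25, which was not called, changed sign with RLE factors (0.013), DESeq2 (0.013), without medium replicate 1 (0.105) and without TL1A replicate 1 (0.16), with a range of -0.192 to 0.16 over the libraries left out, and Vil1, not called, without medium replicate 1 (0.492) and without TL1A replicate 2 (0.223), with a range of -0.561 to 0.492; the cause was not tested. The number of lists called was 9, 8 to 10 with a library left out, 11 over single-row genes, 13 with fry, which does not compare a list with other genes, and 0 with an estimated correlation. The form with an estimated correlation had little power for so few libraries. The lists called by fry and not by camera were the TNF receptors (0.00703), cell cycle (0.00703), glycolysis (0.0193) and JAK-STAT lists (0.0251). Lists not called changed direction in 4 cases: ILC2 markers with limma-voom (0.985) and without TL1A replicate 1 (0.978; 0.454 to 0.978 over the libraries left out), and ILC3 identity genes without TL1A replicate 2 (0.979; 0.722 to 0.999 over the libraries left out) and over single-row genes (0.493); these values are adjusted p. Depth limits genes under about 10 reads per library, and the counting per transcript limits genes with several transcripts regardless of depth.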

Other observations

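The tests in this part were chosen after the results were seen, except those of the genes with almost no reads. Those were not part of the plan fixed before the data were examined either, because they rest on the rows being transcripts. Further gene families were picked after their members' values were seen, so their p-values are no independent evidence. Each call was lost with an estimated correlation, a form of the test with little power for so few libraries. Of 35 proteasome subunit genes tested, 25 rose and none fell (camera, adjusted p = 4.81e-05; adjusted p = 0.24 with an estimated correlation), with Psmb7 at a log2 fold change of 2.09 (SE 0.08) and a family median of 0.41. Of 14 aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 10 rose and 1 fell (adjusted p = 0.0129; 0.24 with an estimated correlation); Iars rose by 1.30 (SE 0.08) and Dars fell by 0.70 (SE 0.11). Of 11 tubulin genes 8 rose and 2 fell (adjusted p = 1.77e-05; 0.24 with an estimated correlation), led by Tuba1a at 2.46 (SE 0.08). Of 8 chaperonin subunit genes 6 rose and none fell (adjusted p = 0.0149; 0.24 with an estimated correlation). The 70 cytosolic ribosomal protein genes did not stand apart from other genes (adjusted p = 0.823, 10 higher and 5 lower), and neither did 36 ribosome biogenesis genes (adjusted p = 0.109, 13 higher and 1 lower). Several ribosomal protein genes were barely counted. Rpl11 had 19 and 31 reads in medium and 20 and 26 with TL1A, and Rpl23a had 6 and 15, then 12 and 14. Rpl4, in contrast, had 19762 and 22357 in medium. The family result therefore does not show that ribosomal protein expression stayed unchanged.

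Of 3 granzyme genes tested 2 rose and 1 fell: Gzmc rose from 10 and 8 reads to 2480 and 2633 and Gzmb from 11 and 3 to 117 and 134, while Gzma fell from 72 and 80 reads to 13 and 13. Of 9 regulators of G protein signalling 4 fell and 1 rose (adjusted p = 0.027; 0.24 with an estimated correlation), with Rgs2 going from 141.3 ± 7.27 to 8.81 ± 0.097 CPM and Rgs10 at -3.51 (SE 0.25). Of 12 serpin genes 4 fell and 3 rose (adjusted p = 0.184): the neutrophil protease inhibitor gene Serpinb1a had a log2 fold change of -4.06 (SE 0.08) and Serpina12, with 1 read in each medium library, had 209 and 203 with TL1A. Some cytokine reads lay in single libraries: Ccl4 had 85 reads in medium replicate 2 and 0 to 2 elsewhere, and Ccl3 had 50 there and 2 or 3 elsewhere, whereas Il5 was low in only 1 library, with 6 reads in medium replicate 1 against 109, 119 and 81.

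Of 268 genes with several tested transcript rows, 12 had rows that changed unequally (edgeR diffSpliceDGE, adjusted p under 0.05), and 2 of these had 1 row that rose and 1 that fell: Tnfrsf25, given with its values among the receptor genes, and Ccr6. In Ccr6, a chemokine receptor gene of ILC3s, NM_001190333 fell by 0.95 (SE 0.16) and NM_009835 rose by 0.43 (SE 0.13), with an adjusted p of 0.00701 for the difference.

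Medium replicate 1 and TL1A replicate 2 shared an excess in one set of genes. Over 3170 genes with a mean log2 CPM above 6, the differences between the libraries of each group correlated at -0.539, across genes, and 38 genes were at least 1.4-fold higher in both of these libraries against 0 in both others; Uqcrc1 was 2.53-fold higher in medium replicate 1 and 1.82-fold higher in TL1A replicate 2, and Nfkbia 2.12-fold and 1.5-fold. GC content and transcript length explained little of it (R squared 0.025), which argues against them as the cause. It held among single-row genes (correlation -0.549, bootstrap interval over genes -0.591 to -0.505), which argues against reads split between transcript rows. The interval covers the sampling of genes only, not that of libraries. A shared preparation or source of these libraries stays open. A block for that pairing called 4734 genes against 4168 with group only, a gain under the 1.5 times set for this explanation. The pairing was chosen from these same differences, so a gain in calls is no support for a shared batch. No label names such a batch, so it cannot be told apart from other causes.

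The rise of Ifng, Gzmb and Ccl5 could come from a different cell mixture or from a change within ILC3s. A larger share of NK cells or ILC1s in the TL1A libraries, which the sort for the IL-23 receptor reporter should largely remove, stays open. Of the 4 other tested markers of the ILC1 and NK cell list 2 fell (Gzma and Klrk1, the latter not with each library left out). Tbx21 (23 and 11 reads to 39 and 32) and Prf1 (44 and 7 to 120 and 61) passed as higher only when adjusted over the list alone. Ncr1, which these cells also carry, rose. A smaller share of ILC3s in the TL1A libraries would raise markers of every other cell type and lower ILC3 identity genes alike. Of 18 tested identity genes, 9 fell, 5 rose and 4 did not pass. On the log2 scale Il23r fell by 0.63 (SE 0.06) and Zbtb16 by 3.03 (SE 0.27). These unequal changes argue against a smaller share as the only cause for the genes of that list. Whether it had a part was not settled by the markers of other cells. Of 18 myeloid and ILC2 markers 5 fell and 2 rose, and 2 of 5 T cell markers fell. Both tested B cell markers (Blk and Cd79b) rose. Some falling markers may be transcripts of the sorted cells. In medium, Fcer1g had 1640 CPM against 5.1 for Csf1r. Cd4, which some ILC3s carry, had 372.3 CPM against 0.599 for Cd3e. The count of falling markers of other cell types therefore cannot decide. A change within ILC3s, which the design names through TL1A, remains a hypothesis, found and examined on the same data; loss or growth of a subset of the sorted cells was not tested.

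Several well-known genes had almost no counted reads: Nfkbiz, Myc, Stat3, Irf7 and Xbp1 had 0 reads in all 4 libraries. Among members of the 14 pathway and ILC3 lists, 38 of 66 genes with several deposited rows had a mean under 10 reads, against 14 of 175 single-row genes (odds ratio 15.3, 95% interval 7.1 to 35, Fisher's exact test p = 2.59e-15), which is consistent with reads of shared exons being set aside as ambiguous. The test of processed pseudogenes stayed open, with 1 of 6 single-row genes that have a named pseudogene under 10 reads against 13 of 169 without (odds ratio 2.38, interval 0.0472 to 23.8, Fisher's exact test p = 0.398), because only 6 genes of these lists could be used. Single-row ribosomal protein genes with few reads, such as Rpl11, lay outside these lists and were not part of the test. Absence of barely counted genes from the changed genes is therefore no measurement of their expression.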
